A study of Mus musculus with 11 samples.

How the data were processed

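Trimethylation of lysine 9 of histone H3 (H3K9me3), a mark of heterochromatin, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in the nucleus accumbens, a striatal region of the reward circuit, of male C57BL/6J mice. Per the labels' protocols, mice received 7 daily intraperitoneal injections of saline or of cocaine at 20 mg/kg, and tissue was taken 24 h after the last injection. Each ChIP pooled 20 tissue punches from 5 mice, per the labels' protocols. Libraries were made from 20 ng of DNA, cut from a gel at 175 to 225 bp and amplified with 21 PCR cycles, per the labels' protocols. The 11 libraries fell into 3 groups: saline ChIP (n = 3), cocaine ChIP (n = 2) and input DNA, the sheared chromatin before precipitation (n = 6). The labels of the inputs name no treatment, so the inputs formed 1 group. The labels number the replicates without saying which mice entered which pool, so all p-values measure the spread between these libraries.

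The authors deposited, for each library, a list of single aligned reads of 35 bp with chromosome, start, end and strand. The raw read counts used here are numbers of these deposited reads per genomic interval, without any normalization by the authors. Every read carried the same match code, per the deposited files, and a score column held the same value in every line and was not used. The build was mm9 for the ChIP libraries, per the submitters' processing notes, and the aligner and its settings are not given in the sources used here. No build was named for the inputs. Their highest read positions lay within 4482 bp of those of the ChIP libraries on each of 21 chromosomes, and 10143 of the 10198 bins without ChIP reads also held no input reads. The inputs listed reads on unplaced sequences (0.233% ± 0.022 of reads, SD, n = 6) and the ChIP libraries listed 0, so ChIP and input reads differed in at least 1 upstream step. Reads on unplaced sequences were left out.

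Reads were placed by their 5' end, and 1 read was kept per position and strand, because ChIP libraries held many reads at repeated positions. Counts were summed in bins of 10 kb over chromosomes 1 to 19, X and Y. Levels are given in CPM, counts scaled to the same total of kept reads in every library. Differences were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (glmQLFit with robust estimation, glmQLFTest), with TMM normalization and the default filter on low counts, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are relative to the rest of each library, since the amount of precipitated DNA was not measured in these files. The comparisons were saline against input, cocaine against input and cocaine against saline, each fitted with the libraries of its 2 groups only. Standard errors of log2 fold changes are the fold change divided by the square root of the F statistic. DESeq2 1.42.0 was run as an alternative.

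The share of a library's reads in enriched bins, in the 10 Mb next to the centromere (starting at 3 Mb on chromosomes 1 to 19 and X) and on each chromosome was compared between cocaine and saline with an exact 2-sided permutation test. With 2 libraries against 3 there are 10 splits, and the smallest p this test can give is 0.2. Enriched bins were those called higher in the 5 ChIP libraries than in the 6 inputs. Domains were made from bins at least 1.5-fold over input (glmTreat), joined across gaps of up to 1 bin, and those of at least 100 kb were counted, a definition made after the data were seen. Mouse chromosomes are acrocentric, so the start of each assembled sequence lies next to the centromere.

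The comparisons, tests, alternatives and the rule for the regions named in the text were chosen before the data were examined. The rule took, per comparison and direction, the 10 regions with the largest log2 fold change among bins with an adjusted p under 0.05, a mean of at least 20 reads per library and no overlap of the values of both groups. Bins no more than 1 bin apart formed a region, which was represented by its bin of smallest p. Where fewer than 5 regions passed, the 5 bins of smallest p in that direction were named instead. Fosb and members of gene lists were to be named as well. Tests on gene bodies, promoters and gene lists had been planned on the condition that an mm9 annotation was at hand, and the only gene table used here is of GRCm38.p6. Those tests were not run, no gene or repeat names were laid over the positions, and the table served only to count named genes per chromosome.

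Alternatives covered other scalings (DESeq2 size factors in edgeR, library size only), no filter on low counts, all deposited reads, bins of 2 and 50 kb, a threshold of 1.5-fold, leaving out each library, the replicate number as a block, a fit of all 11 libraries and a test of enriched bins only. A further 8 were added after the data were seen, among them 1 Mb windows, domains and the bins of typical input depth. The edgeR step was tested on simulated data in which 200 bins were changed, with counts drawn from the means and library sizes of the real libraries at a dispersion of 0.0025. For cocaine against saline, 31% of bins changed by 2-fold and 5% of bins changed by 1.5-fold were recovered at 10 kb, against 96% and 65% at 50 kb. For saline against input at 10 kb, 63% and 7% were recovered, and for cocaine against input 39% and 8%. In the real comparisons with input far more bins differed than the 200 simulated ones. The adjusted threshold was less strict there, so these shares do not give the recovery of the real input comparisons. Among unchanged simulated bins, 0 of the 10 kb and 14 of the 50 kb bins were called for cocaine against saline, 2 for saline against input and 3 for cocaine against input. Tables were handled with the R package data.table, version 1.17.8, and with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 in Python 3.11.15, and figures were drawn with matplotlib 3.10.9.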

Results

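Between 12250479 and 14668860 reads were listed for each of the 5 ChIP libraries and between 5142603 and 10227447 for each of the 6 inputs. After 1 read was kept per position and strand, the saline libraries held 7742435, 7334952 and 5815501 reads, the cocaine libraries 7189307 and 5791298, and the inputs 4794184 to 9514173. Reads at repeated positions made up 47.2%, 47.1% and 52.5% of the saline reads and 43.5% and 58.5% of the cocaine reads, against 6.59% to 9.68% of the input reads. A 10 kb bin held a median of 3.62 CPM in the inputs. All library pairs within a group differed by more than counting error over 50 kb bins, with a chi-square per degree of freedom of 1.11 to 1.21 within saline, 1.15 within cocaine and 1.05 to 1.36 within input. Pairs of a saline and a cocaine library gave 1.08 to 1.26, about the range within groups, and pairs of a ChIP library and an input gave 34.6 to 51.7.

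In saline-treated nucleus accumbens, H3K9me3 lay in many short stretches and fewer broad domains on every chromosome and took 58.1% ± 0.82 of the reads (SD, n = 3) in enriched bins, chosen for holding more ChIP than input reads, which held 23.8% ± 0.78 of the input reads (SD, n = 6). The comparison asked where the mark lies in the control tissue. Of 242890 bins tested against input, 91687 were higher (917 Mb) and 89953 were lower (899.5 Mb). These calls are relative to the typical bin, so they give neither the absolute extent of the mark nor absolute depletion. Bins of 2 kb gave 149 Mb and 167 Mb, but the filter on low counts left only 184510 of them, 74271 higher and 83630 lower. They cover a smaller part of the genome, so the extents at both bin sizes are not comparable. The strongest regions lay on chromosomes 12, 18, 7, 4, 13 and 17. On chromosome 12 (20640001 to 20930000) the leading bin from 20900001 held 20.2 CPM ± 0.88 in saline and 0.830 CPM ± 0.34 in input, a log2 fold change of 4.58 (SE 0.19, edgeR adjusted p = 8.98e-124). On chromosome 18 (36970001 to 37190000) the leading bin held 27.6 CPM ± 3.91 against 1.19 CPM ± 0.33, a log2 fold change of 4.52 (SE 0.17, edgeR adjusted p = 2.28e-153).

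Chromosome 7 held 4 of the 10 named regions: 50310001 to 50540000 (log2 fold change 4.51), 48700001 to 48860000 (4.46), the bin from 33090001 (4.43) and 49070001 to 50010000 (28.5 CPM ± 3.19 in saline against 1.42 CPM ± 0.32). A further region of chromosome 12 (19620001 to 19970000) reached 4.57. The others were chromosome 4 from 111570001 to 112690000 (4.48), chromosome 13 from 62230001 to 62510000 (4.45) and chromosome 17 from 18010001 to 18220000 (4.43). These 10 leading bins held 0.379 to 1.65 CPM in the inputs, below the median bin, and input and ChIP reads differed in an upstream step. Among bins whose pooled input count lay between 0.5 and 2 times its median, a restriction chosen after the data were seen, the highest were chromosome 18 from 37560001 to 37700000 (34.8 CPM ± 3.18 against 1.81 CPM ± 0.41, log2 fold change 4.27, SE 0.15) and chromosome 4 from 146710001 to 146730000 (63.5 CPM ± 4.60 against 3.64 CPM ± 0.58, 4.11, SE 0.13). That restriction left 61376 of 188410 bins higher and 68549 lower.

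**Figure D1:**
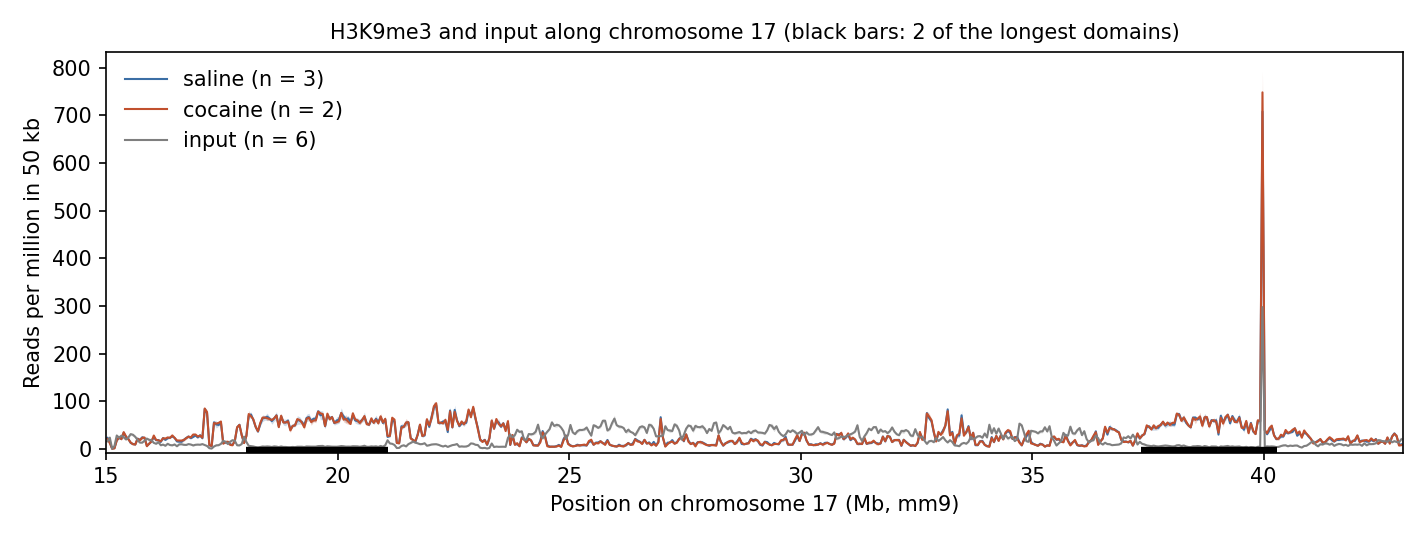
Level (CPM) in 50 kb bins along chromosome 17 (15 to 43 Mb, mm9; lines are group means and bands 1 SD) for saline (n = 3), cocaine (n = 2) and input (n = 6), with black bars under 2 of the longest domains. Both ChIP groups rise together over the domains from 18010001 and from 37350001, where saline held 12.3 and 6.26 times the input level, the latter 10.2 times without the peak from 39950001, which is also high in input (708 CPM in saline and 297.5 CPM in input).

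Bins at least 1.5-fold over input in the 5 ChIP libraries formed 15694 stretches, most of them short. Of these, 1510 were domains of at least 100 kb, which covered 366 Mb with a median length of 160 kb. The longest, on chromosome 17 (18010001 to 21080000), spanned 3070 kb and held 3659 CPM ± 284 in saline (n = 3), 3636 CPM ± 139 in cocaine (n = 2) and 298 CPM ± 31.6 in input (n = 6). The next in length lay on chromosome 17 (37350001 to 40290000, 6.26 times the input in saline, or 10.2 times without its 50 kb of highest input), chromosome 12 (114480001 to 117310000, 9.91 times), chromosome 2 (85390001 to 88010000, 3.53 times), chromosome 4 (111570001 to 114010000, 12.4 times) and chromosome 13 (60880001 to 62950000, 10.8 times). Domains covered 23.6% of chromosome 7 and 23.4% of chromosome 17, but 6.84% of chromosome 18 and 7.65% of chromosome 11. On chromosome Y, where the last read lay at 2902450, they covered 45.5%.

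The most depleted region of the saline comparison was on chromosome 1 (24610001 to 24630000). Its leading bin held 485 CPM ± 76.4 in the inputs (n = 6), far above the median bin, and 10.6 CPM ± 2.04 in saline (n = 3), a log2 fold change of -5.50 (SE 0.17, edgeR adjusted p = 3.19e-221). Saline also lay above its own median bin of 3.31 CPM, so this fold rests on the high input. The other 9 depleted regions ranged from -4.83 to -4.65, lay on chromosomes 11, 18, 12, 10, 7 and 9 and held 9.24 to 14.4 CPM in the inputs, above the median bin. Among bins of typical input, the most depleted were chromosome 11 from 74530001 (0.294 CPM ± 0.15 against 6.63 CPM ± 0.59, log2 fold change -4.42, SE 0.34) and chromosome 7 from 129240001 (-4.26, SE 0.33). In chromosome 11 from 70310001 to 70590000 the leading bin held 0.433 CPM ± 0.48 in saline and 13.0 CPM ± 1.83 in input (log2 fold change -4.83, SE 0.28). Chromosome 18 from 35820001 to 36620000 (-4.82), chromosome 12 from 109120001 to 109810000 (-4.78) and chromosome 10 from 79970001 to 81110000 (-4.69) were long depleted stretches. So were chromosome 7 from 19470001 to 20360000 (-4.67) and from 25630001 to 26240000 (-4.65).

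In cocaine-treated tissue the mark took 58.7% ± 0.99 of the reads in enriched bins (SD, n = 2). Against the same inputs, and again relative to the typical bin, 86167 of 243764 bins were higher (862 Mb) and 85954 were lower (859.5 Mb). Bins of 2 kb gave 169.7 Mb and 177 Mb, and bins of typical input 561 Mb higher, each from a smaller part of the genome (231919 and 188415 bins tested). The highest named region was chromosome 13 from 61090001 to 61180000, where the leading bin held 15.8 CPM ± 1.52 in cocaine and 0.513 CPM ± 0.28 in input (log2 fold change 4.93, SE 0.24, edgeR adjusted p = 8.37e-83). The same bin held 11.9 CPM ± 0.87 in saline. Chromosome 17 from 22570001 to 22690000 followed (24.8 CPM ± 3.02 against 0.939 CPM ± 0.39, 4.78, SE 0.20), and the chromosome 12 bin from 20900001 was named here too (21.9 CPM ± 3.01, 4.68, SE 0.20). Chromosome 7 held 4 of the 10 regions, with log2 fold changes of 4.42 to 4.56 in the bins from 50070001, 50440001, 69860001 and 49830001. The rest lay on chromosome 4 in the bins from 145220001 (4.60) and 113620001 (4.49) and on chromosome 12 in the bin from 20830001 (4.47). These bins held 0.461 to 1.42 CPM in the inputs, below the median bin. Among bins of typical input, the highest were chromosome 18 from 37690001 (37.0 CPM ± 0.35 against 1.81 CPM ± 0.41, log2 fold change 4.36, SE 0.17) and chromosome 17 from 95210001 (4.17, SE 0.15).

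The most depleted bins of cocaine against input lay on chromosome 8 from 129110001 (0.225 CPM ± 0.07 against 13.7 CPM ± 2.33, log2 fold change -5.72, SE 0.39), chromosome X from 71520001 (-5.58, SE 0.59) and chromosome 4 from 117800001 (-5.49, SE 0.46). These levels lie near the floor, with 0.139 CPM in cocaine 1 and 0 in cocaine 2 for the X bin. In saline the same bins held 0.626, 0.394 and 1.27 CPM, also below the inputs, and none of them was called for cocaine against saline. The chromosome 1 bin from 24620001 was among the 10 again (12.5 CPM ± 3.98, -5.23, SE 0.22). The other 6 lay between -5.45 and -5.11, on chromosomes 11, 7, 3, 5, X and 12. Of 241437 bins tested in both comparisons, 79138 were higher in both, which was 93.6% of the cocaine calls, and 81210 were lower in both (94.6%). Independent lists of these sizes would share 31698 and 31990. The log2 fold changes correlated across bins with r = 0.976 and a covariance of 2.03. Simulated groups that shared the inputs were drawn from the input profile, and so carried no mark. They gave r = 0.295, a covariance of 0.0165 and 0 calls. The 0 calls were built in, so this simulation shows only what the shared inputs add. Bins are not independent replicates. With inputs 1 to 3 set against saline and 4 to 6 against cocaine, 71415 bins were higher in both (90.4%) and 74550 lower in both (92.9%). The log2 fold changes then had r = 0.957 and a covariance of 2.03.

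**Figure D2:**
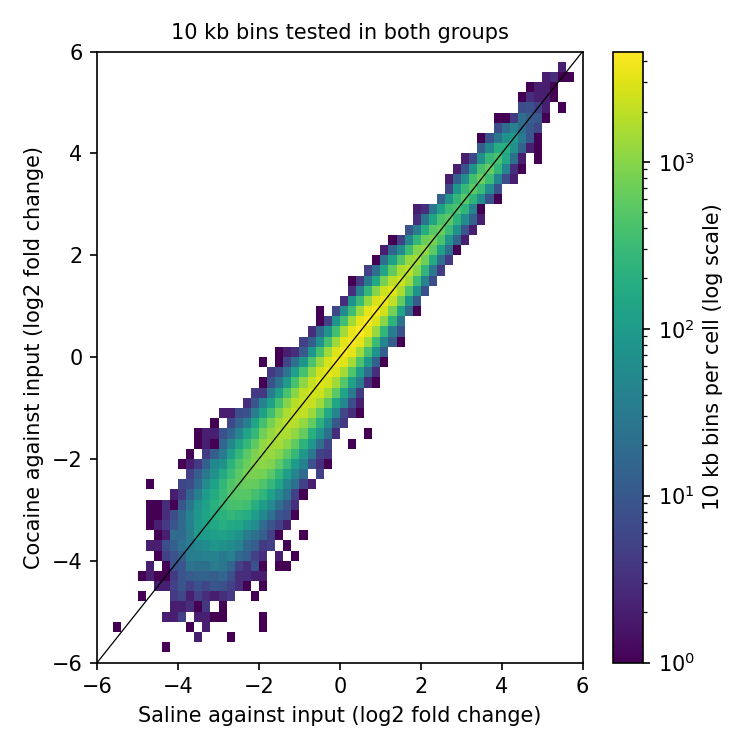
Density of 10 kb bins by the log2 fold change of saline against input (x axis) and of cocaine against input (y axis), coloured by the number of bins on a log scale, with a line where both are equal. The bins lie along the line, with a correlation of 0.976 across bins, part of which comes from the inputs shared by both axes.

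The main contrast of the design asked whether repeated cocaine shifted H3K9me3. In 234164 bins of 10 kb, 0 were higher and 1 was lower in cocaine than in saline (edgeR, adjusted p under 0.05), and DESeq2 called 0. At an unadjusted p under 0.05 there were 11065 bins (4.73% of those tested) with edgeR and 864 with DESeq2. The DESeq2 number lies far below the share expected without any change. Its test was strict here, so its 0 calls are a weak check. The 1510 domains had a median log2 difference of 0.00 between cocaine and saline, and 95% of them lay between -0.12 and 0.12. Of these domains, 50 had an unadjusted p under 0.05 with 0 called by edgeR. Domain counts were scaled within the domains alone, which builds in a median near 0. A shift shared by all domains could therefore not appear there, and only differences among domains were tested. The longest domain, on chromosome 17, differed by -0.03 (edgeR adjusted p = 0.996), and the domain on chromosome 3 from 3330001 to 5220000 by 0.06 (edgeR adjusted p = 0.996). Windows of 1 Mb gave 75 of 2584 at an unadjusted p under 0.05 and 0 called by edgeR, with 95% of their log2 differences between -0.07 and 0.06. At this depth simulated 2-fold changes of 10 kb bins were recovered in 31% and those of 50 kb bins in 96%, and 0 of 50780 bins of 50 kb were called by edgeR (2245 at an unadjusted p under 0.05).

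The called bin was the one on chromosome X from 166420001 to 166430000, near the distal end. It held 76.8 CPM ± 20.1 in saline (n = 3), 50.5 CPM ± 2.77 in cocaine (n = 2) and 49.2 CPM ± 4.90 in input (n = 6), a log2 fold change of -0.58 (SE 0.10, edgeR adjusted p = 0.0051). The bin before it held 58.2 CPM ± 17.7 in saline and 42.8 CPM ± 0.89 in cocaine. The call ended without saline 3 (log2 fold change -0.36, edgeR adjusted p = 0.999) and also without saline 2, cocaine 1 or cocaine 2, with a replicate block, with all deposited reads, with all 11 libraries, among enriched bins alone and with DESeq2. The log2 fold change was -0.36 with the replicate block as well, and -0.68 to -0.54 in the others, about its size with all libraries. Over the alternatives its adjusted p ranged from 1e-05 (edgeR, without saline 1) to 1 (DESeq2). The other 9 bins named for their small p did not pass. The lower ones were chromosome 11 from 69820001 (log2 fold change -0.83, edgeR adjusted p = 0.302), chromosome 2 from 108590001 (-1.01), chromosome 6 from 126810001 (-0.77) and chromosome 1 from 39000001 (-1.31). The higher ones were chromosome 6 from 38230001 (0.92, edgeR adjusted p = 0.777), chromosome 12 from 95440001 (1.01), chromosome 5 from 62490001 (1.23), chromosome 2 from 89740001 (0.94) and chromosome 3 from 92620001 (0.79).

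**Figure D3:**
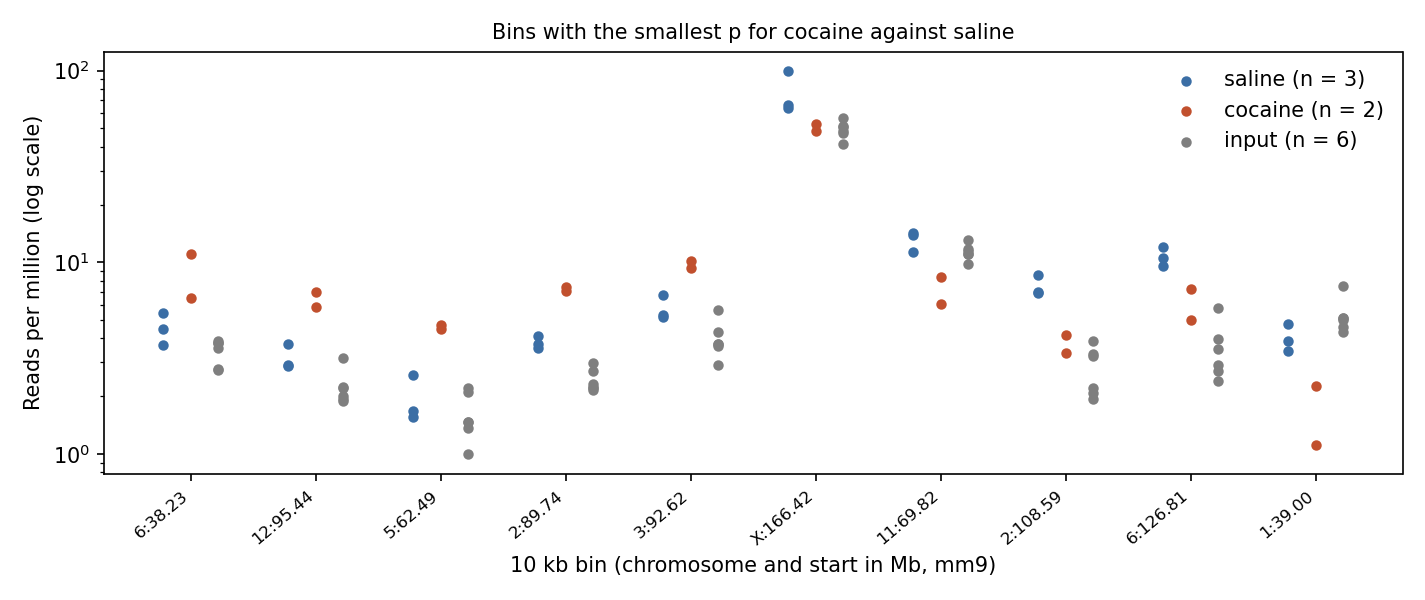
Level (CPM, log scale) of each library in the 10 kb bins with the smallest p for cocaine against saline; points are single libraries of saline (n = 3), cocaine (n = 2) and input (n = 6). Of these bins only that of chromosome X from 166420001 passed the adjusted threshold, with 76.8 CPM in saline and 50.5 CPM in cocaine.

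The share of reads in enriched bins was 58.1% ± 0.82 after saline (n = 3) and 58.7% ± 0.99 after cocaine (n = 2), a difference of 0.630 percentage points that was smaller than the spread between replicates (exact permutation test, 2-sided, p = 0.6). It was 0.171 without saline 1, 1.33 without cocaine 1 and -0.068 without cocaine 2. In the proximal 10 Mb of chromosomes 1 to 19 and X it was 8.35% ± 0.08 after saline and 8.39% ± 0.05 after cocaine (exact permutation test, p = 0.8), against 6.79% ± 0.04 of the input reads (n = 6). That difference turned to -0.0127 percentage points without saline 1 and to -0.00444 without cocaine 2. The 10 deepest bins held 10.3% ± 1.34 of all saline reads, 10.02% ± 0.11 of all cocaine reads and 0.521% ± 0.08 of all input reads. This design cannot give an exact p under 0.2.

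**Figure D4:**
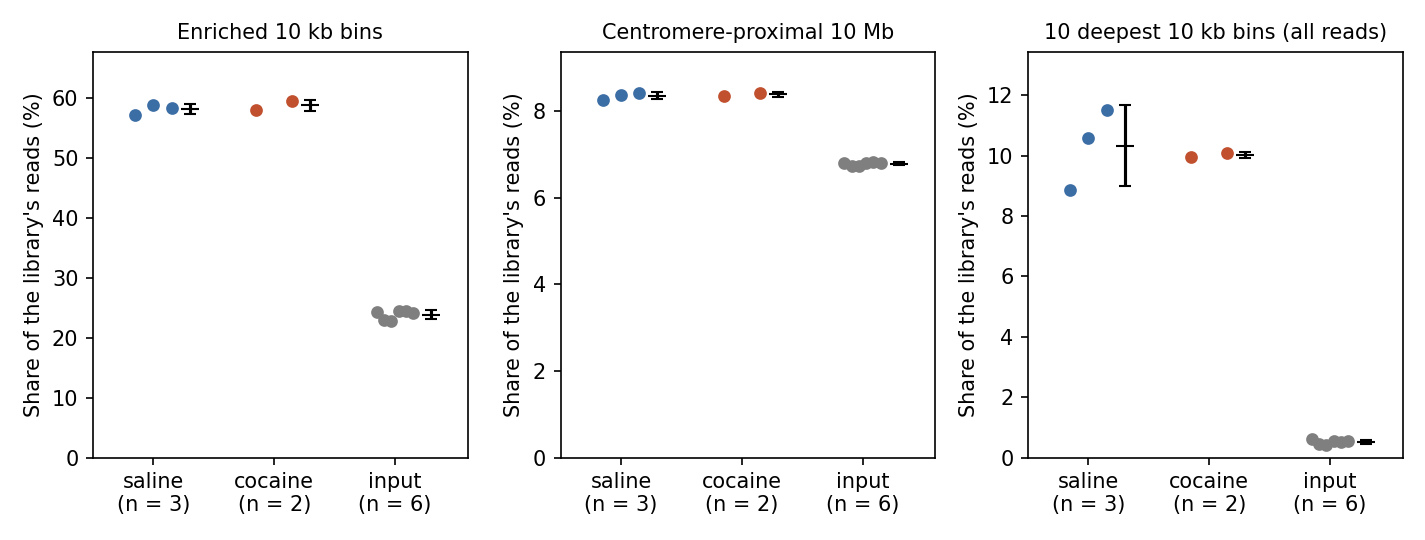
Share of each library's reads in enriched 10 kb bins, in the centromere-proximal 10 Mb and in the 10 deepest bins; points are libraries, and bars show the mean and 1 SD of saline (n = 3), cocaine (n = 2) and input (n = 6). Saline and cocaine overlap in all 3 panels and both lie above the inputs, which the choice of bins by ChIP level fixed for enriched and deepest bins but not for the proximal 10 Mb.

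Chromosomes differed in their share of ChIP reads against input, from which a difference in read placement was not separated. Chromosome 7 took 6.86% ± 0.14 of the saline reads and 5.57% ± 0.04 of the input reads, chromosome 13 5.13% ± 0.02 against 4.47% ± 0.02, and chromosome 17 4.32% ± 0.06 against 3.85% ± 0.03. Chromosome X took 3.02% ± 0.03 against 1.96% ± 0.05, and chromosome Y 0.0994% ± 0.0077 against 0.0120% ± 0.0013. Lower shares than in input were found for chromosome 11 (4.86% ± 0.01 against 6.01% ± 0.07), chromosome 2 (6.74% ± 0.04 against 7.76% ± 0.02) and chromosome 9 (4.86% ± 0.01 against 5.49% ± 0.03). In all, 9 of 21 chromosomes lay above and 10 below every input in the 3 saline libraries. Between cocaine and saline no chromosome differed by more than 0.0207 percentage points. The libraries of both groups did not overlap for 2 of 21 chromosomes (9 and 11), where chance gives 20%, and the smallest exact permutation p was 0.2 (adjusted p = 1).

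**Figure D5:**
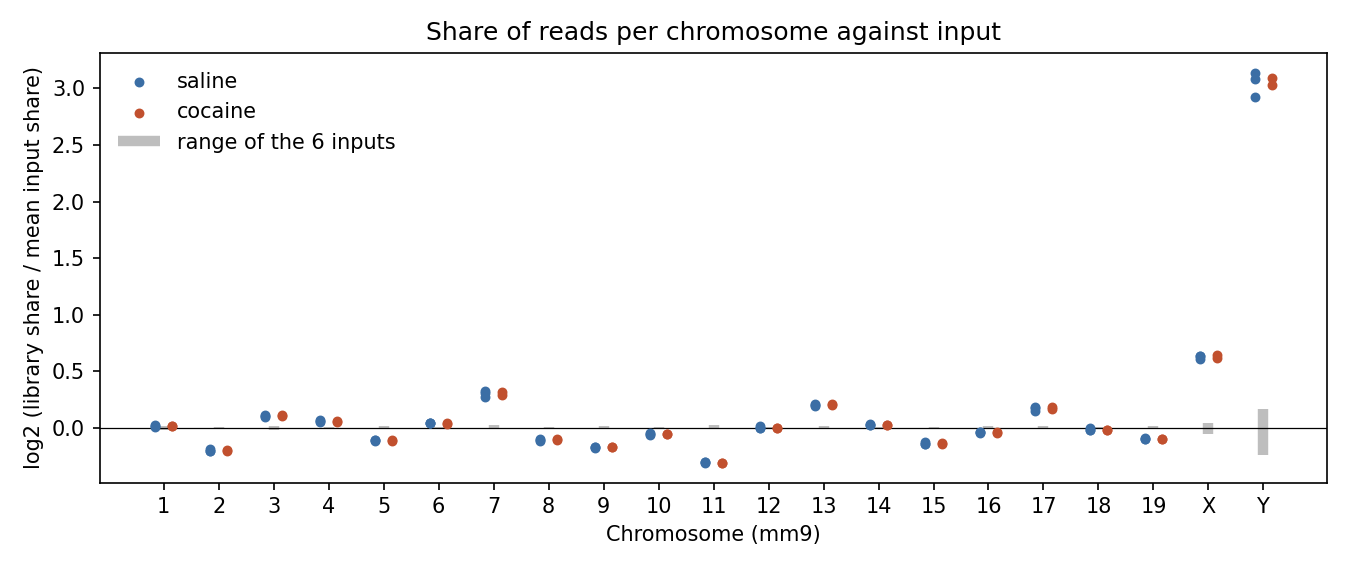
Share of reads per chromosome as log2 of the ratio to the mean input share; points are the 3 saline and 2 cocaine libraries, and grey bars the range of the 6 inputs. Chromosomes 7, 13, 17, X and Y lie above the inputs and chromosomes 2, 9 and 11 below them, with saline and cocaine points close together on each.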

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

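No test in this part was chosen after its result was seen. Among the 6 inputs, the highest library stood apart from the others in 3 named bins, out of 56 bins and 28 library measures looked at, and chance alone sets apart about 1 in 20. Input 3 held 10.01 CPM in the chromosome 4 bin from 117800001, where the others held 7.12 to 7.91. Input 3 also held 7.51 CPM in the chromosome 1 bin from 39000001, where the others held 4.31 to 5.13. Input 6 held 3.15 CPM in the chromosome 12 bin from 95440001, where the others held 1.88 to 2.22. With 3 and 2 libraries, the ChIP groups were too small for this comparison, and no biological explanation was tested.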

How the results depend on the processing

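The alternatives on bins of typical input, domains, 1 Mb windows, the removal of saline 3 together with cocaine 2, the contrast to other bins and the 10 deepest bins were chosen after the data were seen. Against input, the genome called higher or lower stayed within 1.5 times its extent under the other scalings, no filter, 50 kb bins, all reads, DESeq2, the 1.5-fold threshold and a replicate block. Each scaling left the median log2 fold change near 0 (0.0354, 0.0535 and 0.0143 in saline). The scalings therefore did not test how far the extents depend on that centring. With 2 kb bins it fell to 149 Mb higher and 167 Mb lower in saline and to 169.7 Mb higher and 177 Mb lower in cocaine. The filter on low counts left 184510 and 231919 bins of 2 kb there, so a smaller part of the genome was tested. The bins of typical input left 561 Mb higher in cocaine, from fewer bins tested. The share of reads in enriched bins also depended on bin size. Enriched 2 kb bins, out of 98449 tested, held 15.5% ± 0.56 of the saline reads, 15.6% ± 0.37 of the cocaine reads and 2.62% ± 0.08 of the input reads. With 1 library left out the higher calls ranged from 856 to 913.5 Mb in saline and from 731 to 859 Mb in cocaine, where the lone cocaine library left was assumed to vary like the inputs.

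For cocaine against saline 1 bin was called with either other scaling, no filter, 2 kb bins and without saline 1. Calls fell to 0 without each other library (range 0 to 1), with a replicate block, 50 kb bins, all reads, all 11 libraries, enriched bins only, saline 3 and cocaine 2 both left out, domains, 1 Mb windows and DESeq2. Where the X bin was refitted without its call, its log2 fold change stayed at -0.68 to -0.54, apart from -0.36 without saline 3 and with the block and -0.31 without saline 3 and cocaine 2. The cause was not tested. The replicate numbers were not shown to pair libraries (correlation of deviations 0.0506 and 0.0567 for the 2 pairs of saline and cocaine). Saline 2 and cocaine 2 shared 1.24% of positions, more than any other ChIP pair (0.869% to 1.06%), and had the lowest chi-square of these pairs, while saline 1 and cocaine 1 shared 1.01%. With the replicate number as a block 0 bins were called and 11536 had an unadjusted p under 0.05. The cocaine less saline share in enriched bins ranged from -0.068 to 1.33 percentage points with 1 library left out, was negative without cocaine 2, and was -0.302 in the 10 deepest bins. The proximal share ranged from -0.0127 to 0.0702 and was negative without saline 1 and without cocaine 2 (-0.00444). All 20 named bins each of saline and cocaine against input kept direction and call in 320 and 303 refitted values. The called bin of cocaine against saline kept its call in 4 of 14 refits, and the other 9 named bins passed in 0 of 124. Gene body, promoter and gene list alternatives were not run. Depth limits the 10 kb comparison of cocaine with saline.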

Other observations

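The tests of copy ratio and of ranks in the deepest bins, the test of bins without input reads and the comparison of the X bin with bins of like depth were chosen only after the values were seen. A few short stretches held a large part of each ChIP library. With all deposited reads, the bin on chromosome 2 from 98500001 to 98510000 took 8.21% ± 1.07 of the saline reads (n = 3), 7.95% ± 0.09 of the cocaine reads (n = 2) and 0.400% ± 0.06 of the input reads (n = 6). The next deepest were chromosome 9 from 35110001 (0.774% ± 0.11 of saline reads, 17.4 times the input share) and 4 neighbouring bins of chromosome 9 between 3000001 and 3040000 (0.162% to 0.301%). Bins on chromosomes X, 11 and 12 completed the 10, and those of chromosomes 11 and 12 began between 3050001 and 3110001, next to the centromere. H3K9me3 is known to mark the satellite repeats around mouse centromeres.

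The 10 bins took 19.8 times the input share in saline. They were chosen by their ChIP depth, and ChIP and input reads differed in an upstream step, so this ratio does not decide about extra DNA copies alone. For these stacks, the ranks argue against fragments copied by PCR separately in single libraries as the source of most of them. The 10 most stacked positions held 1.103% to 84.2% of the reads of a bin (median 25.1%), which alone decided nothing about PCR. But 10 of the 10 bins ranked among the 20 deepest in each of the 5 ChIP libraries. Copying that favours the same fragments in every library would recur as well, so it was not excluded. The bins were also picked by depth in these same libraries. In 2 of the bins, chromosome X from 139910001 (80.96%) and chromosome 12 from 3110001 (84.2%), few positions held most reads. Any copying by PCR stays open there although 2 of the 2 recurred in each library. Tandem copies of the mouse major satellite unit were tested by the spacing of read starts, which peaked at the length of that unit in 0 of the 10 bins. Spacings of 50 to 400 bp were searched, and many peaks lay near the lower edge, as at 50 bp in the chromosome 9 bin from 35110001. No stretch of known satellite was tried, so this decides nothing about the major satellite. The major satellite, extra DNA copies, other repeats, reads of many near-identical copies gathered in 1 place by the reference, and a high level of the mark in them stay open. They were not separated here and may act together.

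Reads of the ChIP libraries and the inputs were listed differently for unplaced sequences, which raised the question of a looser placement of ChIP reads as the whole cause of high folds where inputs hold few reads. Of the 10853 bins with 0 pooled input reads, 0 reached the median pooled ChIP count of 112, but 10143 were empty in the ChIP libraries too, so this decides nothing. The median pooled ChIP count was 51 in bins with 4 to 10 input reads, 86 with 11 to 20, 97 with 21 to 40 and 126 with 41 to 80, and sorting bins by input builds a higher ratio into the lower classes whatever the cause. In bins of low input a looser placement and a high level of the mark cannot be told apart, since no genome sequence was used here.

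The bin lower after cocaine at the distal end of X, where the mouse X is known to hold the pseudoautosomal region shared with Y, might reflect unequal DNA copy number between pools, which was left undecided. The spread of the 6 inputs over counting error was 2.90 per degree of freedom there, at percentile 98.2 of all bins, the comparison planned. That spread was larger in deep bins (median 3.84, against 0.928 in all bins), and the bin lay at percentile 27.8 of only 18 bins with 0.5 to 2 times its input count. A single deviating library as the whole cause was not excluded. Saline 3 held 99.9 CPM, saline 1 64.1 CPM and saline 2 66.4 CPM. A log2 fold change of -0.36 remained without saline 3, and the call ended there. The bin was chosen for its small p with all libraries, so a remainder in that direction decides nothing. An effect of cocaine on this bin stays open as well and was not separated from copy number, because no input is labelled with a treatment. The 84 splits of the 9 saline and input libraries, run on every 10th bin, gave 1 with as many calls, the real one (18032 bins), and the highest of the others was 0. Every other split mixed saline and input libraries, which raises the spread within its groups. The 0 calls there therefore do not exclude chance by themselves. All 18 pairs of a saline library and an input gave a chi-square per degree of freedom of 34.6 to 51.74 over 50 kb bins. Pairs within saline reached at most 1.214 and pairs within input 1.364. These values argue against a chance division of the libraries, but do not separate the mark from the upstream step.

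It was asked whether the difference between autosomes follows the gene families known to lie in H3K9me3 domains, using counts of named genes per chromosome from the GRCm38.p6 table and the ratio of ChIP to input shares. Over 19 autosomes, the density of vomeronasal receptor genes (356 genes) correlated with the ratio (Spearman rho = 0.752, permutation p = 0.00032, adjusted p = 0.00128 over 4 relations; Pearson r = 0.750, permutation p = 0.00044). Without chromosomes 7 and 17, the farthest from the median, r was 0.526 (permutation p = 0.0466) and rho 0.653. The density of zinc finger protein genes gave rho = 0.111 (permutation p = 0.654) and r = 0.594 (permutation p = 0.0151), which fell to 0.0377 without chromosomes 7 and 17 and so rests on them. Olfactory receptor genes (rho = -0.144, r = -0.0349) and all protein-coding genes (rho = -0.232, r = -0.0467) showed no relation past the threshold. The predicted positive relation with olfactory genes was not met between chromosomes. Totals of 19 autosomes cannot exclude the mark at the olfactory genes themselves. The protein-coding relation was left undecided. A candidate explanation is that clusters of vomeronasal receptor genes, or the repeats among them, carry much of the mark in this tissue, which these chromosome totals cannot place at the genes themselves or separate from read placement.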
